A study of Mus musculus with 26 samples.

How the data were processed

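Gene expression was measured on 26 arrays of 22626 probe sets, per the labels, in WT and Kin- S49 cells that were untreated or had received the cAMP analog for 2, 6 or 24 h. The values are the processed scores that the authors deposited in a single table with 1 column per array; the method and software behind these deposited scores, and their scale, are not given in the sources used here. Groups were taken from the labels, 4 arrays for each untreated group and 3 for each treated one, and arrays are named by the array numbers in the labels. In the labels the times 0, 2, 6 and 24 h follow each other in WT arrays 1 to 4, 16 to 19 and 36 to 39. They do so too in Kin- arrays 5 to 8, 40 to 43 and 44 to 47, while arrays 13 and 14 are untreated only. The labels do not say whether such a series pairs its arrays. The main fit is unpaired, and these series were tried as a block among the alternatives.

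The scale was worked out from the deposited scores themselves. They run from 0.375 to 267, with column medians from 29.1 to 30.6, too narrow for a linear intensity and too high for a logarithm, and 0 values are missing or at or below 0. Among genes with several probe sets that passed, the size of a change was set against the level of the probe set (slope ± SE; probe sets at a level of at least 5). At power 0.5 of the value the slopes were −0.51 ± 0.11 for WT at 2 h, −0.44 ± 0.07 at 6 h, −0.21 ± 0.06 at 24 h and −0.40 ± 0.16 between the untreated lines. At power 0.75 they were −0.01 ± 0.11, 0.06 ± 0.07, 0.29 ± 0.06 and 0.10 ± 0.16, flatter in 3 of these 4 comparisons, and with untransformed values 0.49, 0.56, 0.80 and 0.60. With genes chosen by a mean change of at least 1 instead, power 0.5 gave −0.44, −0.19, 0.05 and −0.63 and power 0.75 gave 0.06, 0.32, 0.56 and −0.12. A logarithm gave slopes between −0.97 and −1.67. These slopes argue against a linear reading put through a logarithm and do not choose the square root over power 0.75. The square root was taken as a log2 intensity for its range, from 0.612 to 16.4 with column medians from 5.40 to 5.53; this is an assumption, so a change of 1 unit may not be an exact doubling, and with it the design written before the scale was known (log2 or linear values) was applied unchanged. The quantiles of the columns differed by at most 4.71% of the interquartile range of 5.52, under the limit of 5%, so the authors' normalization between arrays was kept.

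Probe sets were named from the platform's gene annotation. Of 22626 probe sets 20380 have 1 gene symbol, 691 have several and 1555 have none, and none was named from a probe set with several symbols; 20351 of the 20380 were matched by gene ID to a current gene table, where 0 symbols differed. For 4956 of 12393 genes there was more than 1 probe set, and the one with the highest mean over the 26 arrays stood for the gene in lists and in the text. The symbol Prkar2b had no probe set of its own.

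The arrays were examined for sets that the groups do not explain. After group means were removed, the first component, with 35.5% of the remaining variance, separated the 10 arrays numbered 1 to 14 (highest score −14.3) from the 16 arrays numbered 16 to 47 (lowest score 6.23). Every group held arrays of both. Treated groups held a single array numbered 1 to 14, and untreated groups more than that. The root mean square difference between arrays of a group ran from 0.170 to 0.454, with a median of 0.226 within a set and 0.336 across sets, so no pair of arrays was a copy of another. This set was added as a fixed term, and each set was analysed alone, after the data had been seen.

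A linear model with 1 mean per group and a spread shared by all groups was fitted to every probe set with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with no covariate, for the 3 WT times against 0 h, successive WT times, the 3 Kin- times against 0 h, untreated Kin- against WT, and the difference of the WT and Kin- responses at each time. Benjamini-Hochberg adjusted p under 0.05 counted as passed, and a change of at least 1 log2 unit as large; the median SE was 0.119 log2 units for a treated group against its untreated one. Gene lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry from limma on 1 probe set per gene. The correlation was estimated without a term for the array set, so it includes the difference between the array sets. There were 29 lists with 851 genes, 10 of them in more than 1 list, and 28 had at least 5 measured genes and were tested. The lists were PKA subunits and inhibitors, phosphodiesterases, G protein and cAMP signalling, CREB and immediate-early targets, G1 cyclins with Cdks and Rb/E2F, CDK inhibitors, DNA replication, mitosis and G2/M, Myc family, ribosome biogenesis, ribosomal proteins, pro-apoptotic and anti-apoptotic BCL2 families, caspases and death receptors, p53 targets, T-lineage identity, T-cell activation and NF-kB targets, interferon response, cholesterol synthesis, glycolysis, oxidative phosphorylation, amino acid response and tRNA synthetases, ER chaperones, cytosolic and mitochondrial chaperones, circadian clock, and B-cell, myeloid, erythroid and fibroblast markers. Figures and tables were made with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

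The groups, comparisons, tests, lists, most alternatives and the rule for named genes were chosen before the data were examined. The rule names, for the WT times against 0 h and for untreated Kin- against WT, the 10 largest rises and the 10 largest falls that passed and whose arrays do not overlap between the groups; for other comparisons the 5 largest of each; for each list up to 4 passing members with the largest change, or up to 2 with the smallest p; and Prkaca, Prkacb, Prkar1a, Prkar1b, Prkar2a, Crem, Nr4a1, Myc, Ccnd3, Cdkn1b and Bcl2l11 throughout. Not every gene that the rule allows is described in the text.

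The alternatives planned were quantile normalization, median centring, leaving out dim probe sets or genes, array weights, the series or runs of array numbers as a fixed or random block, fits of only the groups compared, trended and robust variances, 1 probe set or the mean of probe sets per gene, an estimated correlation and fry for lists, and leaving out each array in turn. Added after seeing the data were the set of arrays 1 to 14 against 16 to 47 as a term, each set alone, the values read as linear with a floor at the 20th, 5th or 35th percentile before log2, and the untransformed values. Simulated data had the real spread, 22626 probe sets and 200 changed probe sets in each of 5 simulations. The changed ones all had a middle level, and noise was drawn independently for each array, without the array sets. The fit was tested on these data. For Kin- at 24 h it called 31.6%, 82%, 98.8% and 100% of changes of 0.5, 1, 2 and 4 log2 units, with 52 unchanged probe sets called over the 5 simulations, and for WT at 24 h 34%, 79.2%, 98.8% and 100%, with 41. Exact permutation tests were two-sided. No column of values was left out.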

Results

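S49 is a mouse T-lymphoma cell line whose growth and survival respond to cyclic AMP (cAMP), and Kin- is an S49 variant known to lack the activity of protein kinase A (PKA), the main kinase that cAMP activates. Messenger RNA of wild-type (WT) and Kin- cells was measured on 26 oligonucleotide arrays of 22626 probe sets, which cover 12393 named genes. The cells were left untreated (0 h) or exposed to 100 µM 8-CPT-cAMP, a cell-permeable cAMP analog, for 2, 6 or 24 h. Each line had 4 untreated arrays and 3 arrays at each of the 3 later times, so there were 8 groups, and the number of arrays limits the precision of every value. No untreated arrays were matched to the later times. Nothing in the labels says that arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The scale of the deposited values is not stated; their square root was used as a log2 intensity because of its range. A power of 0.75 made changes depend less on level in some comparisons, so every level and change given in log2 units, and every count at 1 log2 unit, rests on that choice. Arrays numbered 1 to 14 and arrays numbered 16 to 47 formed separate sets within every group, and counts of probe sets and medians of many called lists are also given with a term for this set or within each set. Adjusted p-values come from limma for genes and from camera for gene lists, and a gene is represented by its brightest probe set.

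WT cells at 2 h were compared with untreated WT cells to ask which transcripts respond early to the analog. Crem, which encodes cAMP-responsive activators and the repressor ICER, rose by 6.07 ± 0.36 log2 units (SE; adjusted p = 2.49e-10), from 4.14 ± 0.07 (SD, n = 4) to 10.21 ± 0.74 (SD, n = 3). Sgip1, an endocytosis adaptor best known from neurons, had the largest rise, 6.86 ± 0.305 (adjusted p = 3.99e-12), from 3.88 ± 0.53 (SD, n = 4) to 10.73 ± 0.46 (SD, n = 3). The immediate-early transcription factor gene Fos rose by 5.78 ± 0.39, Rgs2, a regulator of G protein signalling, by 5.45. The orphan nuclear receptor gene Nr4a1 rose by 4.14 ± 0.36, to 12.28 ± 0.23 (SD, n = 3) from 8.13 ± 0.72 (SD, n = 4). The largest fall was that of Ptcra, the pre-T-cell-receptor alpha chain, which fell by 4.60 ± 0.52 (adjusted p = 1.69e-06), to 4.54 ± 1.04 (SD, n = 3) from 9.15 ± 0.46 (SD, n = 4). Rag1, a recombinase of antigen receptor genes, fell by 2.69 ± 0.20, Notch1, a receptor of T-cell commitment, by 2.16. The growth regulator gene Myc fell by 2.46 ± 0.31 (adjusted p = 8.58e-06), to 8.04 ± 0.27 (SD, n = 3) from 10.49 ± 0.45 (SD, n = 4). Tceal1, Vps37b, Irgm2, Maged1, Sgtb and Nabp1 completed the 10 largest rises, between 4.25 and 5.28, and Chdh, Ccnb1ip1, Plxdc1, Il10, Dtwd1, Aldh1b1 and Trim2 fell by between 3.75 and 2.35.

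Of the 42 measured CREB and immediate-early targets, 17 rose, 2 fell and 23 did not pass at 2 h, or 18 and 2 adjusted over the list alone. They included the phosphatase gene Dusp1 with a rise of 4.03 and the transcription factor gene Nfil3 with 3.94. The list was called higher (median 0.28, adjusted p = 9.41e-10), with adjusted p = 0.274 with an estimated correlation; its median was 0.27 with the array-set term, 0.49 in arrays 16 to 47 and 0.27 in arrays 1 to 14. Ribosome biogenesis genes, which build ribosomal subunits in the nucleolus, were called lower. The median was −0.41 (adjusted p = 1.27e-14; adjusted p = 0.616 with an estimated correlation). Of its 54 genes 22 fell, 0 rose and 32 did not pass, or 32 lower adjusted over the list alone, and among them Ppan fell by 1.38, Wdr43 by 1.31 and Gnl3 by 1.19. The median of this list was −0.38 with the set term, −0.43 in arrays 16 to 47 and −0.41 in arrays 1 to 14. Among 22 ER chaperone genes 7 rose and 0 fell, the same counts adjusted over the list alone, with rises of 1.47 for Ero1a and 1.09 for Edem1. The median of 0.25 had adjusted p = 0.0498, and adjusted p = 0.946 with an estimated correlation. It was 0.18, 0.21 and 0.20 with the set term, in arrays 16 to 47 and in arrays 1 to 14.

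Several lists were not called at 2 h but held genes that passed. Among 45 T-lineage genes 9 rose, 11 fell and 25 did not pass, or 9 and 13 adjusted over the list alone, with a median of 0.03, a mean of −0.23 and adjusted p = 0.259; the inhibitory receptor gene Ctla4 rose by 2.98. T-cell activation genes passed more often upward, with 8 of 36 higher and 2 lower (9 and 2 adjusted over the list alone; adjusted p = 0.128), among them the protease gene Gzmb at 2.23. In the interferon list of 31 genes 6 rose and 2 fell, with the GTPase gene Igtp at 3.63 and Irf1 at 2.45, and 5 of 18 circadian clock genes rose, with Per1 at 1.98. Bcl2l11, which encodes the pro-apoptotic protein BIM, rose by 1.71, and Bid, another pro-apoptotic gene, fell by 1.86. The cell cycle inhibitor gene Cdkn1b rose by 1.53 ± 0.36 (adjusted p = 0.00504), while the cyclin gene Ccnd3 had a change of −0.23 (adjusted p = 0.33). Prkar1a, a regulatory subunit of PKA, rose by 0.88 ± 0.10, and the catalytic subunit genes Prkaca and Prkacb had changes of 0.25 (adjusted p = 0.129) and −0.02 (adjusted p = 0.94).

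In all, 3249 probe sets passed at 2 h, 1608 higher and 1641 lower, which is 14.4% of those measured. Of these 886 changed by at least 1 log2 unit, 518 upward and 368 downward. The count was 4308 with the array-set term, 4627 in arrays 16 to 47 alone and 235 in arrays 1 to 14 alone, where a single treated array remained. Array weights gave 6513, with 4177 higher and 2336 lower. Of 489 genes with several probe sets that passed, 44 had probe sets of opposite sign.

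WT cells at 6 h were compared with untreated WT cells to ask what had changed by an intermediate time. Rag1 had the largest fall, with a change of −5.47 ± 0.20 log2 units (adjusted p = 1.55e-13) and a level of 6.08 ± 0.61 (SD, n = 3) against 11.56 ± 0.24 (SD, n = 4). Ramp3, a partner of calcitonin-family receptors that signal through cAMP, rose by 6.36 ± 0.25 (adjusted p = 3.66e-13), from 2.34 ± 0.22 (SD, n = 4) to 8.70 ± 0.15 (SD, n = 3). Wif1, a secreted Wnt inhibitor, rose by 5.87 ± 0.35, Sgip1 by 7.20, Crem by 5.55 ± 0.36 and Lmna, a nuclear lamina gene, by 4.74. The cytokine gene Il10 fell by 4.66, Ptcra by 4.34 and Shmt1, an enzyme of one-carbon metabolism, by 2.97. Tceal1, Maged1, Cd53, Ctla2a and Ctla2b rose by between 4.57 and 5.41, and Ccnb1ip1, Zdhhc14, Trim2, H2-T3, Acot5 and Ifi204 had changes between −3.80 and −2.81. Nr4a1 stood 2.16 above its untreated level (adjusted p = 0.000139) and Fos 4.32, and Myc fell by 2.14 (adjusted p = 3.2e-05).

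Ribosome biogenesis was the list with the smallest p at 6 h. Of its 54 genes 50 fell, 0 rose and 4 did not pass, or 52 lower adjusted over the list alone. With the array-set term the median was −1.16, and it was −1.23 in arrays 16 to 47 and −0.95 in arrays 1 to 14. The median was −1.17 (adjusted p = 3.22e-34; adjusted p = 0.104 with an estimated correlation). Polr1a and Polr1b, subunits of RNA polymerase I, fell by 2.00 and 1.71. Of 36 amino acid response and tRNA synthetase genes 22 fell and 1 rose, also when adjusted over the list alone. The median was −0.65 (adjusted p = 9.15e-08; adjusted p = 0.44 with an estimated correlation). The serine-pathway enzyme gene Shmt2 fell by 1.88 and the glutamine transporter gene Slc1a5 by 1.85; the median was −0.69, −0.79 and −0.59 with the set term and within arrays 16 to 47 and 1 to 14. Cytosolic and mitochondrial chaperones were lower, with 17 of 25 down and 1 up, or 18 and 2 adjusted over the list alone, as in Ahsa1, which fell by 1.06, and Hspa9, by 0.86. The median was −0.44 (adjusted p = 1.62e-07; adjusted p = 0.164 with an estimated correlation). ER chaperones were higher, with 13 of 22 up and 0 down, or 14 adjusted over the list alone, as in Ero1a at 1.98 and Edem1 at 1.30. The median was 0.59 (adjusted p = 3.07e-08; adjusted p = 0.248 with an estimated correlation). The medians of the cytosolic and mitochondrial chaperones were −0.47, −0.49 and −0.41, and those of the ER chaperones 0.57, 0.65 and 0.37, in the same order of fits.

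At 6 h DNA replication was called lower and mitosis higher, with most members of either list not past the threshold. Of 50 replication genes 16 fell and 3 rose, or 19 and 3 adjusted over the list alone, with the uracil glycosylase gene Ung at −2.51 and the thymidine kinase gene Tk1 at −1.10. The median was −0.31 (adjusted p = 0.000191; adjusted p = 0.647 with an estimated correlation). Of 56 mitosis and G2/M genes 16 rose and 0 fell, or 17 and 1 adjusted over the list alone, with the condensin gene Smc4 at 0.86 and Cdc25b, an activator of mitotic entry, at 0.79. The median was 0.28 (adjusted p = 2.24e-06; adjusted p = 0.582 with an estimated correlation). Their medians were −0.30 and 0.29 with the set term, −0.37 and 0.36 in arrays 16 to 47, and −0.25 and 0.18 in arrays 1 to 14. Interferon response genes were higher, with 15 of 31 up and 2 down, or 16 and 2 adjusted over the list alone, led by Gbp2 at 3.97. The medians with the set term, in the later and in the earlier arrays were 0.37, 0.42 and 0.25. The median was 0.36 (adjusted p = 5.46e-05; adjusted p = 0.17 with an estimated correlation). CREB targets stayed higher, with 16 up and 3 down, or 17 and 4 adjusted over the list alone. The median was 0.11 (adjusted p = 0.000328; adjusted p = 0.44 with an estimated correlation). Oxidative phosphorylation genes were called lower, with 13 of 55 down and 1 up, or 14 and 3 adjusted over the list alone, as in Ndufa5, which fell by 0.86. The median was −0.13 (adjusted p = 0.0174; adjusted p = 0.582 with an estimated correlation). In the same order of fits the medians were 0.10, 0.21 and 0.06 for CREB targets and −0.11, −0.13 and −0.08 for oxidative phosphorylation. The G1 cyclin genes Ccne1 and Ccne2 fell by 1.43 and 1.92, in a list of 22 with 7 lower and 2 higher that was not called (adjusted p = 0.0836). Cdkn1b was 1.63 higher (adjusted p = 0.00206) and Ccnd3 had a change of −0.30 (adjusted p = 0.163). Prkaca and Prkar1a rose by 0.33 (adjusted p = 0.0276) and 1.37.

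At 6 h 4441 probe sets passed, 2155 higher and 2286 lower, and 1204 changed by at least 1 log2 unit. The count was 5464 with the array-set term, 4814 in arrays 16 to 47 alone and 719 in arrays 1 to 14 alone; 5 of 793 genes with several passing probe sets had opposite signs among them.

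WT cells at 24 h were compared with untreated WT cells to ask which changes were present after a day of exposure. Sgip1 rose by 8.54 ± 0.305 (adjusted p = 4.9e-14), to 12.41 ± 0.30 (SD, n = 3), and Crem by 5.71 ± 0.36 (adjusted p = 1.58e-10). Bcl2l11 rose by 2.88 (adjusted p = 1.31e-10), from 9.03 ± 0.18 (SD, n = 4) to 11.91 ± 0.58 (SD, n = 3). Tnfrsf18, which encodes GITR, a receptor of the TNF receptor superfamily, rose by 5.24. Ccne2, a cyclin of the entry into S phase, fell by 3.64 ± 0.26 (adjusted p = 7.26e-10), to 5.45 ± 0.78 (SD, n = 3) from 9.09 ± 0.27 (SD, n = 4). The D-type cyclin gene Ccnd3 fell by 1.44 (adjusted p = 5.79e-08), to 9.90 ± 0.15 (SD, n = 3) from 11.34 ± 0.13 (SD, n = 4). Ctla2b, Ctla2a, Olig3, Ramp3, Acer2, Wdr78 and Tceal1 had the other rises among the 10 largest, between 5.38 and 6.70. Ptcra, Rag1, Ifi204, Il10, Shmt1, Cth, Ccnb1ip1, Ung and Chdh fell by between 4.91 and 3.16. Myc fell by 2.12 (adjusted p = 1.4e-05) and Cdkn1b rose by 1.52 (adjusted p = 0.00217), while Nr4a1 had a change of 0.74 (adjusted p = 0.148).

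Lists of the cell cycle were called lower at 24 h. Of 50 DNA replication genes 48 fell and 0 rose, or 48 and 1 adjusted over the list alone, with changes of −2.80 for the origin licensing gene Cdc6 and −2.76 for Gins1. The median was −1.67 (adjusted p = 5.71e-30; adjusted p = 0.0644 with an estimated correlation). Of 56 mitosis genes 52 fell and 2 rose, the same adjusted over the list alone. The median was −1.49 (adjusted p = 2.78e-26; adjusted p = 0.0858 with an estimated correlation). The kinase gene Aurkb fell by 2.88 and Melk by 2.38. Their medians were −1.67 and −1.51 with the array-set term, −2.04 and −1.82 in arrays 16 to 47 and −1.10 and −0.99 in arrays 1 to 14. Among 22 G1 cyclin, Cdk and Rb/E2F genes 14 fell and 2 rose, or 15 and 2 adjusted over the list alone. The median was −0.73 (adjusted p = 1.45e-06; adjusted p = 0.0512 with an estimated correlation). The ubiquitin ligase gene Skp2, which targets p27, fell by 2.72, and the pocket protein gene Rbl2 rose by 2.10. This list's median was −0.70, −0.91 and −0.53 with the set term and in the later and earlier arrays. Among 7 CDK inhibitor genes Cdkn1b alone passed (adjusted p = 0.891 for the list).

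Lists of growth were called lower at 24 h as well. All but 1 of 54 ribosome biogenesis genes fell, 53 by count with 0 higher, or 54 adjusted over the list alone, as in Nolc1, which fell by 2.08, and Gnl3, by 2.05. The median was −1.14 (adjusted p = 3.87e-27; adjusted p = 0.0644 with an estimated correlation). Of 36 amino acid response genes 25 fell and 1 rose, or 26 and 1 adjusted over the list alone, as in Shmt2 at −2.69 and Mthfd2 at −2.24. The median was −1.20 (adjusted p = 4.85e-11; adjusted p = 0.266 with an estimated correlation). The medians of these lists were −1.13 and −1.22 with the set term, −1.35 and −1.55 in arrays 16 to 47 and −0.85 and −0.67 in arrays 1 to 14. Cytosolic and mitochondrial chaperones were lower, with 20 of 25 down and 1 up in either adjustment, including the counts adjusted over the list alone, led by Fkbp4, which fell by 1.92. The median was −0.68 (adjusted p = 1.65e-10; adjusted p = 0.0512 with an estimated correlation). Oxidative phosphorylation genes were lower, with 19 of 55 down and 3 up, or 21 and 4 adjusted over the list alone, as in Uqcrq, which fell by 1.12. The median was −0.17 (adjusted p = 0.00779; adjusted p = 0.421 with an estimated correlation). In the same order of fits the medians were −0.73, −0.76 and −0.58 for the chaperones and −0.13, −0.19 and −0.16 for oxidative phosphorylation. Ribosomal protein genes, with 7 of 37 higher and 2 lower, were not called (adjusted p = 0.106).

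Among lists of signalling and lineage, CREB targets were higher at 24 h, with 17 of 42 up and 2 down, also when adjusted over the list alone (median 0.15, adjusted p = 0.00779). So were G protein genes, with 12 of 34 up and 3 down, in the count adjusted over the list alone too (median 0.10, adjusted p = 0.0293). T-cell activation genes were higher, with 12 of 36 up and 1 down, the same adjusted over the list alone (median 0.18, adjusted p = 0.017), led by Gzmb at 4.16. T-lineage genes were called higher, with 19 of 45 up and 8 down, as when adjusted over the list alone (median 0.02, adjusted p = 0.0404), among them Ctla4 at 4.79 and the chemokine receptor gene Ccr7 at 3.33. Interferon genes had 12 of 31 up and 2 down, or 13 and 2 adjusted over the list alone (median 0.52, adjusted p = 0.0205). Each of these 5 lists had adjusted p = 0.421 with an estimated correlation. With the set term, in arrays 16 to 47 and in arrays 1 to 14 the medians were 0.12, 0.25 and 0.06 for CREB targets, 0.10, 0.16 and 0.13 for G protein genes and 0.19, 0.25 and 0.05 for T-cell activation. They were 0.06, 0.15 and 0.07 for T-lineage and 0.48, 0.38 and 0.29 for interferon. The Myc antagonist gene Mxd4 rose by 3.31 in a Myc family list of 10 genes with 3 higher and 4 lower (adjusted p = 0.891).

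The other lists were not called at 24 h. Among 25 caspase and death receptor genes 9 rose and 3 fell (adjusted p = 0.125), with the translation inhibitor gene Pdcd4 at 2.60 and the receptor gene Fas at 1.29. Of 11 pro-apoptotic BCL2 family genes 2 rose and 1 fell (adjusted p = 0.891). The anti-apoptotic BCL2 family had 4 measured genes, too few for the list test; 0 passed by limma, where Mcl1 had a change of 0.28 (adjusted p = 0.258). Of 21 p53 targets 7 rose and 2 fell (adjusted p = 0.153), with Gadd45a at 3.86 and Btg2 at 2.13, and of 18 circadian genes 7 rose and 0 fell (adjusted p = 0.128). Cholesterol synthesis had 3 of 21 genes higher and 0 lower (2 adjusted over the list alone; adjusted p = 0.848). Glycolysis had 3 of 21 higher and 4 lower (adjusted p = 0.516), and ER chaperones 4 of 22 higher and 6 lower (5 and 9 adjusted over the list alone; adjusted p = 0.516). Of 11 phosphodiesterase genes, which break down cAMP, 3 rose, or 4 adjusted over the list alone (adjusted p = 0.13), with Pde1b at 2.34. Of 8 PKA genes 2 rose and 1 fell (adjusted p = 0.566), as Prkar1a rose by 0.86, Prkacb rose by 0.56 (adjusted p = 0.0178) and Prkar2a fell by 0.68 (adjusted p = 0.0416). Markers of other cell types were not called as lists, with 4 of 15 B-cell genes higher and 1 lower (adjusted p = 0.28), and 2 of 18 myeloid genes higher (adjusted p = 0.641). The erythroid list had 1 of 11 genes lower, or 0 adjusted over the list alone (adjusted p = 0.904), and the fibroblast list 2 of 17 genes higher and 1 lower (adjusted p = 0.646).

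In total 6780 probe sets passed at 24 h, 3261 higher and 3519 lower, with 1316 higher and 1295 lower by at least 1 log2 unit. The array-set term gave 7686, arrays 16 to 47 alone gave 7202 and arrays 1 to 14 alone 3183. Of 1347 genes with several passing probe sets, 25 had opposite signs. The median and mean or the direction of the test differed in sign only for WT lists that were not called. At 2 h these were G protein, Myc family, ribosomal protein, pro-apoptotic BCL2, p53, T-lineage and B-cell. At 6 h they were phosphodiesterase, Myc family, ribosomal protein, pro-apoptotic BCL2, p53, circadian and fibroblast, and at 24 h pro-apoptotic BCL2, cholesterol, myeloid and erythroid.

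**Figure D1:**
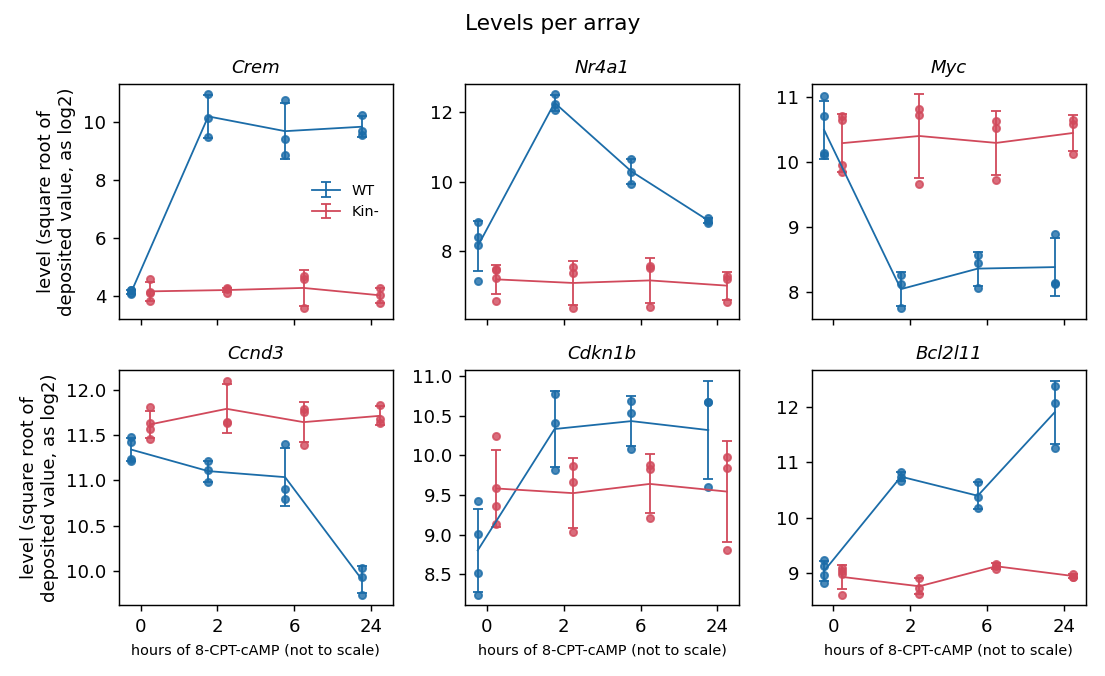
Level of 6 genes on each array, as the square root of the deposited value taken as log2, against hours of exposure (positions not to scale); points are arrays, lines join group means and bars are SDs (n = 4 at 0 h and n = 3 later). In WT, Crem went from 4.14 at 0 h to 10.21 at 2 h and Bcl2l11 from 9.03 at 0 h to 11.91 at 24 h, while no probe set of Kin- passed at any time.

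Successive WT times were then compared to ask when each change took place. Between 2 and 6 h the interferon-inducible GTPase genes Gbp2, Gbp2b and Gbp6 rose by 3.89 ± 0.61, 3.42 ± 0.75 and 3.35 ± 0.895 log2 units, and Iigp1 by 3.02 ± 0.84 (SE). Their arrays at 6 h spread widely, with SDs of 1.63, 2.88, 2.15 and 2.19 (n = 3). Rag1 fell by 2.78 and Shmt1 by 2.21 in that interval, and the transcripts of Nr4a1 (−1.98 ± 0.39, adjusted p = 0.00157), Fos (−1.46), Maff (−2.79) and Per1 (−1.09) came down from their 2 h levels. Sgtb and Stra6 fell by 2.29 and 2.23, and Parp14 rose by 2.69. CREB targets were lower at 6 h than at 2 h, with 9 of 42 down and 1 up, or 11 and 1 adjusted over the list alone. The median was −0.24 (adjusted p = 0.00196; adjusted p = 0.495 with an estimated correlation). Ribosome biogenesis was called lower, with 34 of 54 down, or 39 adjusted over the list alone. The median was −0.55 (adjusted p = 1.01e-15; adjusted p = 0.365 with an estimated correlation). Of the other lists called lower, DNA replication had 11 genes down and 1 up (18 and 1 adjusted over the list alone), amino acid response 14 and 0 (23 and 1), chaperones 15 and 0 (18 and 0) and oxidative phosphorylation 7 and 0 (7 and 0). Called higher were mitosis with 7 genes up and 0 down (7 and 0 adjusted over the list alone), interferon with 10 and 2 (13 and 2), ER chaperones with 7 and 0 (9 and 0) and G protein genes with 6 and 1 (7 and 2). These 8 lists had adjusted p-values from 1.22e-06 to 0.0409, and from 0.365 to 0.861 with an estimated correlation. The array-set term does not alter list medians between times with equal numbers of arrays per set. In arrays 16 to 47 and 1 to 14 the medians were −0.26 and −0.22 for CREB targets, −0.65 and −0.50 for ribosome biogenesis, −0.33 and −0.27 for replication and −0.62 and −0.56 for amino acid response. They were −0.40 and −0.32 for chaperones, −0.24 and −0.08 for oxidative phosphorylation, 0.25 and 0.16 for mitosis and 0.40 and 0.23 for ER chaperones. Interferon genes had medians of 0.21 in all arrays and 0.11 and 0.09 within the sets, and G protein genes changed sign between the sets, with −0.07 and 0.19. At this step 2948 probe sets passed (1441 higher, 1507 lower), against 5180 with the set term, 5363 in arrays 16 to 47 (1835 higher, 3528 lower) and 0 by limma in arrays 1 to 14, where each group has a single array. Without the WT 6 h array 38 the count was 1895, with array weights 7573 (2205 higher, 5368 lower), with the array-number series as a random block 5271 and as a fixed block 5433, and in a fit of only the groups compared 1335.

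Between 6 and 24 h lists of the cell cycle were called lower. Of 56 mitosis genes 53 fell and 0 rose, the same adjusted over the list alone (median −1.81, adjusted p = 5.27e-59). Of 50 DNA replication genes 44 fell and 0 rose, or 45 adjusted over the list alone (median −1.38, adjusted p = 1.71e-39). The G1 cyclin list had 9 of 22 lower and 1 higher, or 12 and 1 adjusted over the list alone (median −0.40, adjusted p = 6.12e-07). These 3 are the only list calls of any comparison that held with an estimated correlation, with adjusted p = 0.0199, 0.0339 and 0.0209. Their medians in arrays 16 to 47 and 1 to 14 were −2.10 and −1.15 for mitosis, −1.63 and −0.81 for replication and −0.48 and −0.27 for G1 cyclins. The kinase genes Melk and Ttk fell by 2.56 and 2.48, Pmf1 by 2.76, Ercc6l by 2.60, the replication factor gene Cdc45 by 2.37 and the cyclin gene Ccna2 by 2.34. T-lineage was called higher, with 16 of 45 genes up and 0 down, or 18 adjusted over the list alone, as in the chemokine receptor gene Ccr9 at 2.52 and Dntt at 1.57. The median was 0.47 (adjusted p = 4.03e-05; adjusted p = 0.103 with an estimated correlation). The medians within the 2 sets were 0.50 and 0.33. ER chaperones were called lower, with 15 of 22 down, or 16 with 1 up adjusted over the list alone, by medians of −1.10 and −0.32 within the sets. The median was −0.83 (adjusted p = 3.74e-10; adjusted p = 0.114 with an estimated correlation). Scg5, the adipocyte regulator gene Pparg, Ms4a4b, Cxcr6 and Plac8 rose by between 3.04 and 4.43, and Bcl2l11 rose by a further 1.51. Gbp2b fell by 3.14, from 6 h arrays that spread widely (SD 2.88, n = 3).

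Among other lists called between 6 and 24 h, the lower ones were amino acid response with 11 of 36 genes down (15 adjusted over the list alone), chaperones with 10 of 25 (13) and glycolysis with 4 down and 1 up (7 and 1). Higher were T-cell activation with 8 up (9 adjusted over the list alone), p53 targets with 5 up and 1 down (8 and 1), B-cell markers with 4 up (4) and ribosomal proteins with 2 up (0). Their adjusted p-values ran from 5.46e-06 to 0.0435, and from 0.114 to 0.681 with an estimated correlation. Medians in arrays 16 to 47 and 1 to 14 were −0.58 and −0.13 for amino acid response, −0.34 and −0.14 for chaperones, −0.06 and −0.33 for glycolysis, 0.19 and 0.23 for p53 targets, 0.11 and 0.04 for B-cell markers and 0.11 and 0.05 for ribosomal proteins. T-cell activation had opposite signs there, with 0.18 and −0.0046. Ribosome biogenesis, with 6 genes lower and 1 higher, was not called (adjusted p = 0.0595). At this step 4028 probe sets passed, 1956 higher and 2072 lower, against 5294 with the array-set term, 5344 in arrays 16 to 47 and 0 by limma in arrays 1 to 14; array weights gave 7322 and a fit of only the groups compared 1883.

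**Figure D2:**
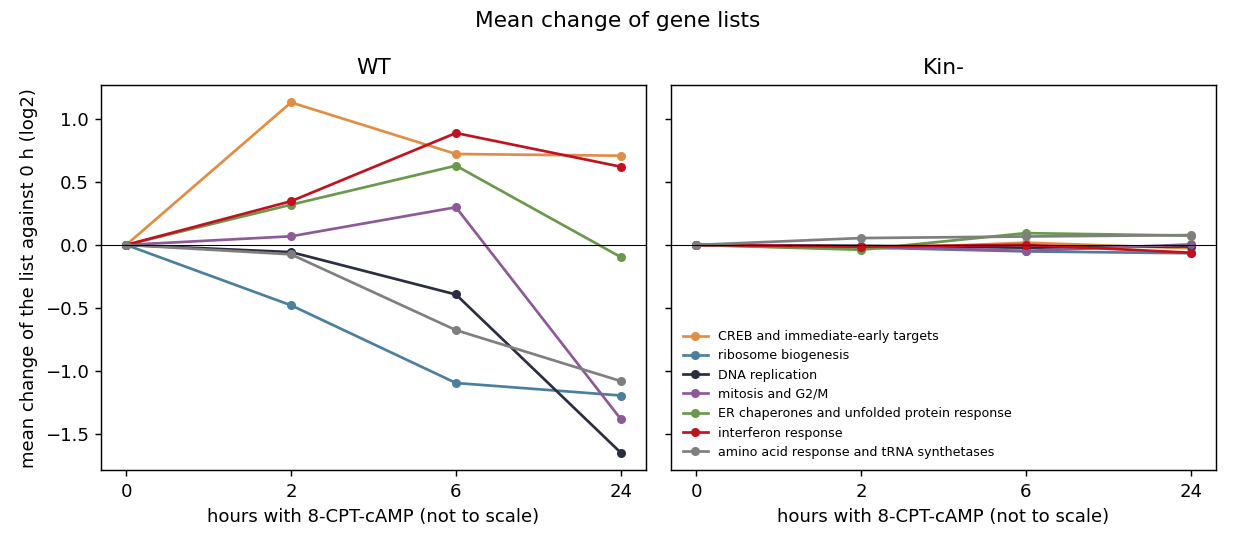
Mean change of 7 gene lists against 0 h in log2 units, WT on the left and Kin- on the right, at 0, 2, 6 and 24 h of exposure (positions not to scale). In WT the DNA replication mean was −0.39 at 6 h and −1.65 at 24 h and the mitosis mean went from 0.30 to −1.38 between these times, while the Kin- lines stay near 0.

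Treated and untreated arrays of Kin- were compared to ask which responses occur without PKA activity. In Kin-, Crem had changes of 0.05 ± 0.36 at 2 h, 0.12 at 6 h and −0.14 at 24 h (SE; n = 3 against 4; adjusted p = 1 at each time). Nr4a1 had changes of −0.10, −0.04 and −0.18 and Myc of 0.11, 0.01 and 0.16 at these times, Fos had a change of −0.53 at 2 h, and none of them passed. By limma, 489, 429 and 491 probe sets had an unadjusted p under 0.05 at 2, 6 and 24 h. These are 2.16%, 1.90% and 2.17% of those measured, below the share of 0.05 given where nothing changes. Shares this low can mean that the test was too strict, since the spread in the main fit includes the difference between the array sets. They are therefore not evidence of no response, and changes may have been missed. After adjustment 0 probe sets passed at these times, the smallest adjusted p being 0.101, 1 and 0.283. The counts were 1, 0 and 0 with a term for the array set, 0 at every time in arrays 16 to 47 alone, in arrays 1 to 14 alone, with untransformed values and with trended, robust variances, and 1, 0 and 0 when the values were read as linear. At 2 h quantile normalization gave 3, median centring 2, the array-number series as a random block 2 and array weights 1; at 24 h array weights gave 1 and leaving out array 8 gave 4. On data simulated at the spread of these arrays, with 3 treated and 4 untreated arrays at 24 h, 31.6% of probe sets changed by 0.5 log2 units were called in Kin-, 82% of those changed by 1 and 98.8% of those changed by 2. These shares are for probe sets of middle level and for noise without array sets, so they may differ in the real arrays. By camera 0 lists were called at 2 and 24 h and 2 at 6 h, against 1, 4 and 5 in arrays 16 to 47 alone and up to 2, 4 and 4 with 1 array left out. In all arrays at 6 h oxidative phosphorylation (median 0.03) and ER chaperones (median 0.10) were called higher, each with adjusted p = 0.0175, and adjusted p = 0.991 with an estimated correlation. None of their 55 and 22 genes passed, and adjusted over the list alone 0 genes of any list passed in Kin- except 1 at 24 h. This was the Myc family gene Mycl, named after its values were seen, with a change of −0.53 ± 0.17 (SE) that did not pass over all genes (adjusted p = 1). The medians with the set term, in arrays 16 to 47 and in arrays 1 to 14 were 0.06, 0.04 and 0.02 for oxidative phosphorylation and 0.07, 0.10 and 0.05 for ER chaperones. Along the direction of the WT response of the same time, where 1 is the mean WT response, the Kin- response was −0.00158 ± 0.0476 at 2 h, 0.0123 ± 0.0374 at 6 h and 0.0116 ± 0.0215 at 24 h (SE; exact two-sided permutation p = 1, 0.83 and 0.657). With the array-set term it was −0.0192 ± 0.0126, −0.00253 ± 0.0111 and 0.00348 ± 0.00532 (SE; exact two-sided permutation p = 0.278, 0.778 and 0.667 over the 18 splits within sets).

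**Figure D3:**
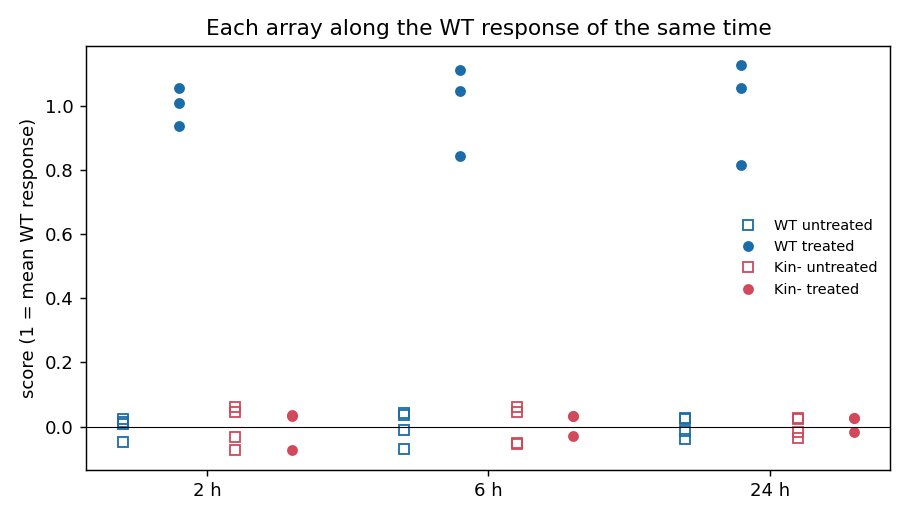
Score of each array along the WT response of the same time, where 0 is the mean of the untreated arrays of its line and 1 the mean WT response; open squares are untreated and filled circles treated arrays of WT and Kin-. The mean score of treated Kin- arrays was −0.00158 at 2 h, 0.0123 at 6 h and 0.0116 at 24 h.

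The difference between the responses of WT and Kin- was tested directly. At 2 h the response of Sgip1 was 6.86 ± 0.43 log2 units higher in WT (adjusted p = 3.01e-09), that of Fos 6.31, of Crem 6.02, of Rgs2 5.59, of Tceal1 5.02 and of Nr4a1 4.25. The differences for Ptcra, Chdh, Plxdc1, Ccnb1ip1, Il10 and Myc were −4.52, −3.81, −2.98, −2.86, −2.67 and −2.57. At 6 h Sgip1 (7.20), Ramp3 (6.54), Wif1 (6.26), Crem (5.44) and Tceal1 (5.31) led the positive differences, and Rag1 (−5.23), Il10 (−4.83), Ptcra (−4.24), Ccnb1ip1 (−3.93) and Trim2 (−3.15) the negative ones. At 24 h the leading differences were 8.20 for Sgip1, 6.68 for Ctla2b, 6.40 for Ramp3, 6.17 for Ctla2a and 5.85 for Crem, and −4.95 for Ptcra, −4.25 for Ifi204, −4.21 for Rag1, −3.87 for Il10 and −3.55 for Ccne2. CREB targets differed at 2 h, with 16 of 42 genes higher and 1 lower, or 18 and 2 adjusted over the list alone (adjusted p = 2.31e-10; adjusted p = 0.225 with an estimated correlation). Ribosome biogenesis differed at 6 h, with 43 of 54 genes lower and 0 higher, or 50 adjusted over the list alone (adjusted p = 2.08e-33; adjusted p = 0.114 with an estimated correlation). DNA replication differed at 24 h, with 45 of 50 genes lower, or 47 adjusted over the list alone (adjusted p = 9.31e-32; adjusted p = 0.0711 with an estimated correlation). Mitosis differed too, with 51 of 56 lower and 2 higher (adjusted p = 1.65e-27; adjusted p = 0.0735 with an estimated correlation). The medians of these 4 lists in all arrays, in arrays 16 to 47 and in arrays 1 to 14 were 0.40, 0.51 and 0.20 for CREB targets, −1.15, −1.24 and −0.85 for ribosome biogenesis, −1.74, −2.04 and −1.15 for replication and −1.48, −1.77 and −1.01 for mitosis.

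Lists called for a difference of responses numbered 3 at 2 h, 9 at 6 h and 11 at 24 h. At 2 h the others were ribosome biogenesis, with 10 genes lower (14 adjusted over the list alone), and ER chaperones, with 2 higher (4), and each had adjusted p = 0.999 with an estimated correlation. At 6 h CREB targets (12 higher and 2 lower), interferon (9 and 2), mitosis (9 and 0) and ER chaperones (6 and 0) were higher in WT, or 13 and 3, 14 and 2, 10 and 0 and 10 and 0 adjusted over the list alone. DNA replication (8 genes lower), oxidative phosphorylation (6), amino acid response (14) and chaperones (13) were lower, or 9, 7, 17 and 17 adjusted over the list alone. At 24 h ribosome biogenesis (48 lower), amino acid response (25), chaperones (18), G1 cyclins (13) and oxidative phosphorylation (12) were lower, or 53, 25, 20, 14 and 14 adjusted over the list alone. G protein genes (12 higher), CREB targets (11), T-cell activation (8) and interferon (7) were higher, or 13, 12, 9 and 8 adjusted over the list alone. With an estimated correlation the adjusted p of these lists ran from 0.16 to 0.695 at 6 h and from 0.0541 to 0.426 at 24 h. Within arrays 16 to 47 and 1 to 14 the median differences included −0.77 and −0.55 for amino acid response and 0.44 and 0.26 for mitosis at 6 h, and −1.31 and −0.79 for ribosome biogenesis at 24 h. T-cell activation at 24 h had 0.28 and −0.08, the only one of these called lists with opposite signs in the 2 sets.

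The probe sets whose response differed numbered 1566 at 2 h (795 higher in WT and 771 lower), 2444 at 6 h (1148 and 1296) and 4859 at 24 h (2306 and 2553). The counts were 2616, 3715 and 6048 with the array-set term, 2428, 3179 and 5708 in arrays 16 to 47 alone, and 1, 1 and 722 in arrays 1 to 14 alone, where treated groups have a single array. Array weights gave 3323 (2093 higher, 1230 lower) at 2 h and 4500 at 6 h, and the array-number series as a random block 2539 and 3667 and as a fixed block 2616 and 3828.

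**Figure D4:**
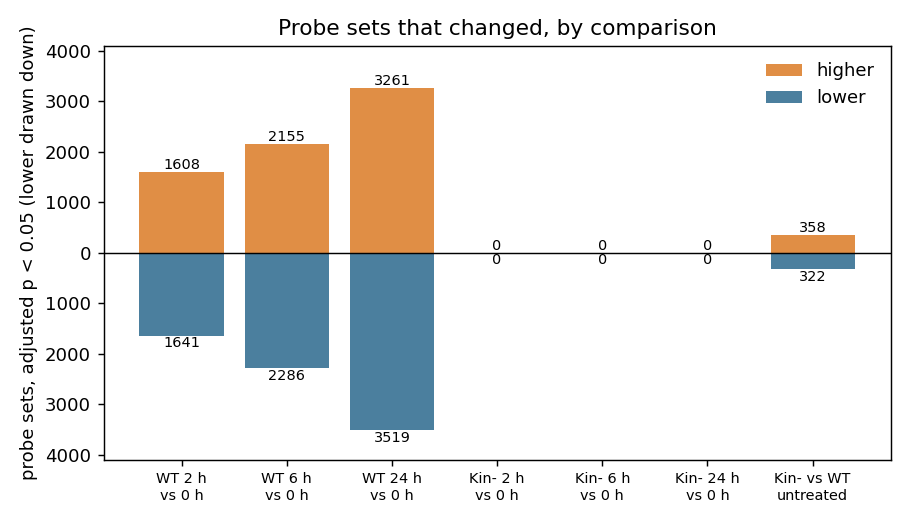
Number of probe sets with adjusted p under 0.05 in each comparison, higher drawn upward and lower drawn downward from 0. WT gave 1608 and 1641 at 2 h and 3261 and 3519 at 24 h, each Kin- time gave 0, and untreated Kin- against WT gave 358 and 322.

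Untreated Kin- and WT cells were compared to ask how the lines differ before exposure. Hes1, a transcriptional repressor downstream of Notch, was lower in Kin- by a change of −4.90 ± 0.16 log2 units (adjusted p = 4.36e-14), at 2.73 ± 0.30 (SD, n = 4) against 7.63 ± 0.31 (SD, n = 4). Ccr9, a chemokine receptor of thymocytes, was lower by a change of −4.66 ± 0.43 (adjusted p = 1.27e-06), and Eps8, Atp8a2, Ifit1, Ppm1m, Scel, Sdc1, Lgals9 and Irf8 had changes between −4.19 and −2.69. Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, was 4.64 ± 0.56 higher in Kin- (adjusted p = 3.68e-05), at 9.96 ± 1.00 (SD, n = 4) against 5.32 ± 0.26 (SD, n = 4). Cyp2c23, Glrp1, the cystathionine lyase gene Cth, Pdgfrb, Gm9222, Tfpi, Nupr1, Plekha1 and Cox6a2 were higher by between 2.83 and 4.19. Arrays of a group spread widely for some genes named here. The SD was 1.92 for Cth in WT, and 1.72, 1.58 and 1.51 for Plekha1, Pdgfrb and Ifit1 in Kin- (n = 4). Transcripts of PKA itself did not pass, with changes of −0.21 for Prkaca (adjusted p = 0.395), −0.03 for Prkacb (adjusted p = 0.999) and −0.22 for Prkar1a (adjusted p = 0.336). Nor did Crem (0.02), Nr4a1 (−0.95, adjusted p = 0.166) or Myc (−0.21) pass, while Pkig, a PKA inhibitor gene, was lower at −1.18.

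Amino acid response and tRNA synthetase genes were higher in untreated Kin-, with 8 of 36 up and 0 down, or 22 adjusted over the list alone, among them the asparagine synthetase gene Asns at 1.19 and Chac1 at 1.40. The median was 0.48 (adjusted p = 6.64e-20; adjusted p = 0.238 with an estimated correlation). T-lineage genes were lower, with 8 of 45 down and 1 up, or 11 and 1 adjusted over the list alone. The median was −0.11 (adjusted p = 0.000206; adjusted p = 0.238 with an estimated correlation). The adhesion receptor gene Cd2 was the member that was higher, at 2.00. Interferon genes were called lower with 1 of 31 down (2 adjusted over the list alone; median −0.13, adjusted p = 0.00143; adjusted p = 0.41 with an estimated correlation). Oxidative phosphorylation was called lower with 4 of 55 down and 2 up (6 and 2 adjusted over the list alone; median −0.11, adjusted p = 0.000561; adjusted p = 0.688 with an estimated correlation). Cholesterol synthesis was called higher with 0 of 21 genes past limma's threshold, in the count adjusted over the list alone as well. The median was 0.36 (adjusted p = 0.000454; adjusted p = 0.898 with an estimated correlation). Stard4 had a change of 0.72 (adjusted p = 0.0877). Glycolysis with 1 gene higher (2 adjusted over the list alone), circadian clock with 2 (2) and ribosome biogenesis with 1 (1) were called higher at medians of 0.23, 0.08 and 0.07 (adjusted p = 0.022, 0.019 and 0.0224; adjusted p = 0.898, 0.587 and 0.906 with an estimated correlation).

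In arrays 16 to 47 and in arrays 1 to 14 the medians were 0.48 and 0.50 for amino acid response, −0.15 and −0.09 for T-lineage, −0.10 and −0.17 for interferon, 0.38 and 0.31 for cholesterol, −0.11 and −0.12 for oxidative phosphorylation and 0.04 and 0.06 for ribosome biogenesis. Those of glycolysis (0.52 and −0.07) and of the circadian list (0.21 and −0.07) had opposite signs in the 2 sets. In all, 680 probe sets passed, 358 higher and 322 lower in Kin-, against 1354 with the array-set term, 1249 in arrays 16 to 47, 0 by limma in arrays 1 to 14, and 450 without the Kin- 0 h array 40. Array weights gave 1685, runs of array numbers as a block 1083 and a fit of only the groups compared 410.

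The WT responses at the 3 times were set side by side, with the reservation that they share 4 untreated arrays. At 2 and 6 h 957 probe sets were higher and 889 lower at both times and 49 went opposite ways, where independent lists of these sizes give 153 and 166. Unchanged groups simulated against the same controls gave 0, which tests little, as few probe sets pass in such groups. At 6 and 24 h 1543 were higher and 1766 lower at both and 144 went opposite ways (311 and 356 for independent lists). At 2 and 24 h 794 were higher, 794 lower and 383 opposite (232 and 255). With separate untreated arrays for each time, 1106 to 1319, 2358 to 2548 and 1018 to 1257 probe sets had the same sign for these 3 pairs. Independent lists give at most 232, 553 and 375 there. Across probe sets, which are not independent replicates, the changes correlated with r = 0.717, 0.759 and 0.470 for these 3 pairs, against simulated values of 0.427, 0.425 and 0.425. With the untreated arrays split into sets of 2, r ran from 0.540 to 0.686, from 0.644 to 0.744 and from 0.361 to 0.453 over 6 splits. The covariances were 0.173, 0.276 and 0.152 against simulated ones of 0.0124, 0.0123 and 0.0123.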

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

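Of the tests in this part, the regroupings that exchange times within each line, the array-set term for the size of the Kin- response and the compression over arrays 1 to 14 were chosen after the results were seen. Successive WT times differed by tests of the difference itself, with 2948 probe sets and 10 gene lists between 2 and 6 h and 4028 probe sets and 12 lists between 6 and 24 h. With an estimated correlation between genes 0 of these 10 lists and 3 of these 12 were called. From 2 to 6 h the genes that rose most were Gbp2 by 3.89, Gbp2b by 3.42, Gbp6 by 3.35, Iigp1 by 3.02 and Parp14 by 2.69, and those with the largest falls were Maff at −2.79, Rag1 at −2.78, Sgtb at −2.29, Stra6 at −2.23 and Shmt1 at −2.21. The 6 h arrays differed widely for Gbp2, Gbp2b, Gbp6 and Iigp1, with SDs of 1.63, 2.88, 2.15 and 2.19 (n = 3). With 1 array left out their rises ran from 3.37 to 4.82, from 2.48 to 5.08, from 2.43 to 4.59 and from 2.38 to 4.28, and those of Gbp6 and Iigp1 did not always pass. From 6 to 24 h Scg5 rose by 4.43, Pparg by 3.76, Ms4a4b by 3.17, Cxcr6 by 3.10 and Plac8 by 3.04, and Gbp2b had −3.14, Pmf1 −2.76, Ercc6l −2.60, Melk −2.56 and Ttk −2.48.

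The WT and Kin- responses differed by the test of their difference for 1566 probe sets and 3 lists at 2 h, 2444 and 9 at 6 h, and 4859 and 11 at 24 h. With an estimated correlation 0 of these lists were called at each time. At 2 h the largest differences, WT minus Kin-, were 6.86 for Sgip1, 6.31 for Fos, 6.02 for Crem, 5.59 for Rgs2 and 5.02 for Tceal1, and −4.52 for Ptcra, −3.81 for Chdh, −2.98 for Plxdc1, −2.86 for Ccnb1ip1 and −2.67 for Il10. At 6 h they were 7.20 for Sgip1, 6.54 for Ramp3, 6.26 for Wif1, 5.44 for Crem and 5.31 for Tceal1, and −5.23 for Rag1, −4.83 for Il10, −4.24 for Ptcra, −3.93 for Ccnb1ip1 and −3.15 for Trim2. At 24 h they were 8.20 for Sgip1, 6.68 for Ctla2b, 6.40 for Ramp3, 6.17 for Ctla2a and 5.85 for Crem, and −4.95 for Ptcra, −4.25 for Ifi204, −4.21 for Rag1, −3.87 for Il10 and −3.55 for Ccne2.

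Among 300 untreated groups of 4 arrays (150 genes named in the text), 12 held an array farther from the others than Dixon's criterion at the 95% level allows, where chance sets apart about 1 in 20 groups. In WT these were Fcgr3 on array 36 (2.93, others 2.79 to 2.81), Gbp2 on array 13 (3.17, others 2.85 to 2.90), Gzmb on array 1 (4.61, others 4.87 to 4.88), Hspa9 on array 13 (12.32, others 12.55 to 12.60), Iigp1 on array 16 (3.15, others 3.81 to 3.87), Pparg on array 1 (4.70, others 3.55 to 3.65) and Vpreb1 on array 1 (2.88, others 2.92 to 2.93). In Kin- they were Ahsa1 on array 44 (11.17, others 11.32 to 11.34), Btg2 and Pdcd4 on array 40 (7.99, others 8.17 to 8.19, and 9.60, others 9.03 to 9.12), and Pparg and Vim on array 14 (4.29, others 3.61 to 3.69, and 11.37, others 12.52 to 12.71).

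Other splits of the same arrays into groups of the same sizes bear on whether the counts of probe sets come from the grouping. For WT at 2, 6 and 24 h the real split alone, 1 of 35, reached its count (3249, 4441 and 6780). The highest others were 1124, 2195 and 4654, all with 3 of the 4 untreated arrays set against the rest, nearly the mirror of the real split. The share of 0.0286 is the smallest that 35 splits can give, so chance is unlikely but not excluded. The same holds between the untreated lines, with 680 in 1 of 35 splits and a highest other of 1. Successive times allow only 10 splits, too few for a share under 0.05, with 2948 against a highest other of 30 and 4028 against 240, each reached by 1 split. In Kin- a real count of 0 is reached by every split (35 of 35), which tests nothing; the highest others were 76, 10 and 14, each of which grouped the untreated arrays 5 and 14 with the treated array of the earlier set and so follows the array sets; the count with the set term was 1 at 2 h and 0 at 6 and 24 h. For the differences of responses, exchanging times within each line gave a count as large in 4, 1 and 4 of 100 splits (highest others 2070, 661 and 5389). That exchange asks whether time matters in either line, so small shares do not by themselves show that the lines differ. Exchanging the lines within times gave a count as large in 7, 12 and 8 of 100 (highest others 2503, 3488 and 6083). Each of these splits parted the treated arrays by line, as the real one does, while the highest count of the remaining splits was 3, 36 and 2. Chance is not excluded by the exchange of lines alone.

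Counts of gene lists called by camera with its preset correlation were mostly not separable from other splits. These splits take no account of the array sets. The Kin- splits with the most lists each grouped arrays of 1 set, namely 40, 44 and 45 at 2 h, 40, 44 and 42 at 6 h and 5, 14 and 8 at 24 h. The WT split with the most lists at 24 h grouped the untreated arrays 1, 13 and 16, nearly the mirror of the real split. For WT 26, 11 and 5 of 35 splits called as many lists as the real 3, 9 and 12, with highest others of 6, 12 and 13. In Kin- at 6 h 22 of 35 did, with 2 lists against a highest other of 6. At 2 and 24 h the real count of 0 lists is reached by every split (35 of 35), which tests nothing, and the highest others were 7 and 8. Between the untreated lines 2 of 35 did, with 8 lists against a highest other of 9. Successive times have too few splits, with 10 lists against 8 and 12 against 9, and 1 split each. For the differences of responses 64, 18 and 16 of 100 exchanges of times (highest others 8, 13 and 12) and 73, 18 and 15 of 100 exchanges of lines (7, 11 and 12) called as many as 3, 9 and 11.

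No probe set of Kin- passed at any time after the analog. A larger spread between Kin- arrays is argued against as the cause, since the median ratio of the Kin- to the WT within-group variance was 0.903 and 45.8% of probe sets had the larger variance in Kin-. A response of the WT kind at a reduced size of 0.05 of the WT response or more is argued against, since with a term for the array set the size along the WT response was −0.0192 ± 0.0126 at 2 h, −0.00253 ± 0.0111 at 6 h and 0.00348 ± 0.00532 at 24 h (SE), under 0.05 by more than 2 SE at each time, while a smaller response stays open. Without that term, as first planned, the sizes were −0.00158 ± 0.0476, 0.0123 ± 0.0374 and 0.0116 ± 0.0215 (exact permutation p = 1, 0.83 and 0.657), errors that include the difference between the array sets. These were not under 0.05 by more than 2 SE at any time, so the argument rests on the term chosen after the results were seen. The sizes were −0.0190, −0.0193 and 0.000868 within arrays 16 to 47 and −0.0195, 0.0227 and 0.0074 within arrays 1 to 14. The lack of kinase activity known of this line is the biological explanation that the design names, and it was not tested separately from other differences between the lines.

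Along the mean WT response of 2 h, array 2 scored 0.936 against 1.008 and 1.056 for arrays 17 and 37. At 6 h array 3 scored 0.843 against 1.112 and 1.045 for arrays 18 and 38. The WT 24 h array 4 likewise had a smaller response than its companions, with a score of 0.817 against 1.127 and 1.056 for arrays 19 and 39. Changes compressed on all arrays of the earlier set may account for it, since the changes of arrays 1 to 14 had slopes of at most 0.838 on those of arrays 16 to 47 in the other comparisons, and ratios of 0.912 and 0.931 at 2 h, 0.832 and 0.773 at 6 h, 0.768 and 0.757 at 24 h and 0.745 and 0.75 between the untreated lines when genes were chosen on separate arrays. RNA of untreated cells mixed into array 4 stays open, as falls of 2 or more lost 40.2% and rises 17.2% of their size, a ratio of 2.34. A culture behind the others in time stays open too, with a slope of 0.706 for genes that change between 6 and 24 h and 0.776 for genes changed at 6 h and not after, a difference of −0.0707 (bootstrap −0.102 to −0.0381). No other biological explanation was tested, since the labels give none for this array.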

How the results depend on the processing

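The array sets 1 to 14 and 16 to 47, each set alone, the linear readings and the untransformed values were tests chosen after the results were seen. Trended and robust variances, leaving out dim probe sets and the untransformed values left every count of probe sets within 1.5 times, and no scaling moved the median of all genes by 0.1 log2 units. For the 779 named gene results that had passed, 14470 alternative values kept their side of the threshold, 1056 no longer passed and 3 turned in sign; for the 319 that had not passed, 5948 still did not and 97 did. The labels do not say whether consecutive array numbers pair arrays, and the main fit is unpaired. The series of consecutive array numbers was fitted as a block, which pairs arrays by series. The array-number series as a fixed term gave no value for the untreated lines. The cause was not tested for any change below except where fewer arrays or genes are named.

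Quantile normalization gave 3 probe sets in Kin- at 2 h and 0 lists in Kin- at 6 h, median centring 2 probe sets in Kin- at 2 h, and each linear reading 1. Array weights gave 6513 in WT at 2 h (4177 higher, 2336 lower, against 1608 and 1641), 7573 for 6 against 2 h (2205 and 5368, against 1441 and 1507), 7322 for 24 against 6 h, 1 in Kin- at 2 h and at 24 h, 1685 between the untreated lines, and 3323 (2093 and 1230) and 4500 for the difference of responses at 2 and 6 h. The array-number series as a random block gave 5271 for 6 against 2 h, 2 in Kin- at 2 h and 2539 and 3667 for the differences at 2 and 6 h, and as a fixed block 5433, 2616 and 3828 for the same comparisons without Kin-. Runs of array numbers as a fixed block gave 1083 between the untreated lines and 1 list in Kin- at 24 h. The array-set term gave 5180 for 6 against 2 h, 1 in Kin- at 2 h, 1354 between the untreated lines, 2616 and 3715 for the differences at 2 and 6 h, and 1 list in Kin- at 2 and at 6 h. Arrays 16 to 47 alone gave 5363 for 6 against 2 h, 1249 between the untreated lines, 2428 for the difference at 2 h (1489 and 939), 7 lists in WT at 2 h and 1, 4 and 5 lists in Kin- at 2, 6 and 24 h. Arrays 1 to 14 alone, with fewer arrays, gave 235, 719 and 3183 in WT, 0 by limma for successive times and between the untreated lines, and 1, 1 and 722 for the differences; the lone treated array of a group was assumed to vary like the other groups. Fits of only the groups compared, with fewer arrays for the spread, gave 1335 and 1883 for successive times and 410 between the untreated lines.

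With 1 probe set per gene, where fewer are tested, the counts were 1987, 2830 and 4081 in WT, 1810 and 2509 for successive times and 1005, 1603 and 3022 for the differences. The mean of probe sets turned the sign of Rps9 in WT at 24 h (−0.29), Xiap for 6 against 2 h (−0.18) and Rps20 in the difference at 24 h (−0.074), and gave 1 list in Kin- at 2 h. An estimated correlation left 0 lists in every comparison where camera had called any, except for 3 for 24 against 6 h. That correlation includes the difference between the array sets. It was not estimated with the array-set term, so these losses cannot be laid to correlation between genes within a set. By fry, which asks another question, 7 lists passed in WT at 2 h, 19 at 24 h, 0 in Kin- at 6 h, 4 between the untreated lines and 1 and 17 for the differences at 2 and 24 h, and the Myc family turned to an adjusted p = 0.0282 in the other direction in WT at 24 h.

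Leaving out 1 array at a time gave 2428 to 3719, 3444 to 4489 and 5899 to 6982 probe sets in WT, 1895 (without the WT 6 h array 38) to 3594 and 3219 to 4466 for successive times, 0 to 1, 0 to 0 and 0 to 4 in Kin- (4 without the Kin- 24 h array 8), 450 (without the Kin- 0 h array 40) to 810 between the untreated lines, and 1248 to 1736, 1799 to 2801 and 4292 to 5307 for the differences. For lists it gave 2 to 3, 8 to 11 and 10 to 12 in WT, 7 to 11 and 8 to 13 for successive times, 0 to 2 (2 without the Kin- 2 h array 6), 1 to 4 (4 without the Kin- 0 h array 44) and 0 to 4 (4 without the Kin- 24 h array 8) in Kin-, 5 (without the WT 0 h array 16) to 8 between the untreated lines, and 2 to 4, 9 to 10 and 10 to 13 for the differences. In Kin- the list count at 2 h was 1 without array 5, 14, 41 or 44, at 6 h 1 without array 5, 42 or 46, and at 24 h 2 without array 14 or 44 and 1 without array 40, and the probe set count was 1 without array 41 or 45 at 2 h and without array 47 at 24 h.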

Other observations

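Of the tests in this part, the permutation test of lists and the reading of the untreated difference as signalling in WT cells were chosen after the results were seen. Several genes outside the leading lists moved with the analog in WT cells. The B-cell surrogate light chain gene Vpreb1 rose by 2.70 log2 units at 24 h and by 2.53 between 6 and 24 h, the signalling adaptor gene Blnk rose by 1.42, and the immunoglobulin heavy chain gene Ighm fell by 2.34. Itgam and Fcgr3, known as myeloid receptors, rose by 2.11 and 1.88, and the filament genes Vim and Acta2 by 1.08 and 1.38. The nuclear receptor gene Rora rose at each time, by 1.44, 1.66 and 2.39. The glucose transporter gene Slc2a3 rose by 2.72, 2.91 and 3.08 at the 3 times, while Pgam1, a glycolytic enzyme, fell by 1.00 and the lactate transporter gene Slc16a1 by 1.07 at 24 h. Genes tied to p53 went both ways, with Trp53inp1 at 2.58 and Sesn1 at 2.19 at 24 h and Aen at −1.15 at 2 h and −1.93 at 6 h.

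Among genes called in both comparisons, most differences of untreated Kin- from untreated WT cells ran opposite to the WT response. Of genes called in both, 116 of 179 at 2 h, 178 of 245 at 6 h and 242 of 293 at 24 h had opposite signs, and across the genes called in the WT response, which are not independent replicates, the changes correlated with r = −0.162, −0.230 and −0.344. The same untreated WT arrays enter both sides, which by itself pushes r upward, to +0.46 in simulations without changes. With these arrays split between the sides r lay between −0.249 and −0.125, −0.362 and −0.167, and −0.429 and −0.303. These ranges, of which −0.125 is the highest value, hold the r of shared arrays, so sharing weighed little among called genes. As sharing only pushes r upward, the split could not test it as the cause of a negative r. The highest r was −0.127 without amino acid genes, −0.0723 within arrays 16 to 47 and −0.130 among genes of middle level. These values argue, weakly, against amino acid genes alone, the array sets and genes near their lowest or highest level as the cause of the sign. No reference value for unrelated real changes was computed, so whether r lies beyond such values was not tested. By ranks the highest r with split arrays was −0.0517, at 2 h. Signalling through the kinase in untreated WT cells, absent in Kin-, stays open like any other difference between these lines, since the value of −0.125 is the pattern itself and tests neither; over all genes the highest value was −0.0682.

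A permutation test of each list's mean change over the 35 splits of the arrays, whose smallest p is 0.0286, does not assume any correlation between genes. At that smallest exact p stood 11 of 28 lists in WT at 2 h (adjusted p = 0.0728), 17 at 6 h (0.0471) and 18 at 24 h (0.0445). The test does not compare a list with other genes, so it cannot tell a change particular to a list from a wide response. In WT at 2 h even the cytosolic and mitochondrial chaperones stood there, with a mean change of −0.027. All lists at the smallest p of a time share an adjusted p, which depends on how many they are. The adjusted values under 0.05 at 6 and 24 h are therefore not separate evidence for each list. In Kin- the smallest exact p of any list was 0.343, 0.143 and 0.143 at the 3 times. Between the untreated lines, over 70 regroupings, 5 lists stood at the smallest exact p (adjusted p = 0.16), namely Myc family, T-lineage, interferon, amino acid response and B-cell markers.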
